A study of Mus musculus with 2 samples.

How the data were processed

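Gene expression was measured on 2 arrays, 1 control and 1 Med1 knockout, each hybridised with RNA of dental epithelial stem cells cultured for 7 days. Med1 encodes a subunit of Mediator, the complex that links transcription factors to RNA polymerase II, and the knockout carries a loxP-flanked allele recombined by Cre under the keratin 14 promoter. Per the series' design text, the cells of each genotype came from 3 mice, and there is a single array per genotype. The RNA of the 3 mice is read here as pooled, which the labels do not state outright. The arrays are Illumina bead arrays, in which biotin-labelled product is read with Cy3-streptavidin, and both sat on 1 chip, so no chip effect separates them, while the position on the chip differs with genotype.

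The deposited non-normalized table holds the mean bead signal intensity of each of 25697 probes on a linear scale, with no normalization between arrays and no visible background subtraction, since the lowest signals are 133 and 139. The deposited detection p-value of each probe compares it with the negative control beads of its array, in 798 steps, per the file headers and the values. GenomeStudio 2011.1 is named in the submitters' processing notes. The deposited value table holds a second set of intensity values for the same probes: its columns share 1 distribution to within 0.28 units, have a median of 199 each and keep the rank order of the non-normalized columns, as quantile normalization would give, and the method is not given in the sources used here.

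From the non-normalized table, background was corrected with the normexp model, with the negative control mean and variance inferred from the detection p-values, an offset of 16 was added, and the log2 values were quantile normalized (neqc in limma 3.58.1, R 4.3.3). A probe counted as detected at a detection p-value under 0.01. Of the probes, 23978 had 1 gene symbol in the platform annotation, 0 had several, and 1719 were unnamed here. The gene identifiers of 23962 probes were found in the mouse gene table. Of the 16593 genes measured, 4777 had more than 1 probe, and each gene was represented by the probe with the highest mean over both arrays. All values below are differences of normalized log2 intensity, knockout minus control, or the folds they give. For a gene detected on 1 array only, the fold is a lower bound, the bright value over the higher of the dim probe's own value and the lowest value of any detected probe on that array (6.30 on the control array and 6.37 on the knockout array), written "at least". It is a bound only for values after this background correction, which widens the differences of dim probes, as it does for other folds with a dim side. Counts of genes at 2-fold use the measured differences, and are given with the lower bounds too where these change them for the groups described.

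With 1 array per genotype there was no test between conditions, no standard deviation and no p-value. Genes were counted as higher or lower at a difference of at least 2-fold when detected on at least 1 array, which is a rule of size. The precision that can be measured is technical. Over 1830 genes with several probes detected on both arrays, the difference had a between-probe standard deviation of 0.31. Probes of near-identical family members, such as those of the Sprr, Lce and Defb families, can share signal.

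Before the data were examined, 30 gene lists and 34 families of gene symbols were fixed, together with the rule for the genes named and the alternatives. The median difference of a list over its detected members was placed among 10000 random lists of the same size drawn from detected genes matched on mean expression in 20 bins. This percentile describes these 2 arrays and is not a test of genotype. It was given for lists with at least 3 detected members. The genes named are Med1, the 12 with the largest difference in each direction among genes detected on both arrays and at least 2-fold different with and without background correction, the 6 with the largest lower bound among genes detected on 1 array in each direction, and up to 4 members of each list and 3 of each family with the largest absolute difference. Predicted genes were passed over. Members named beyond these, said to be added, were chosen after their values were seen.

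Alternatives were no background correction, normexp on the signal alone with offset 50, an offset of 50 in neqc, median scaling, no normalization between arrays, the deposited values, a detection p-value under 0.05, detection on both arrays, no detection filter, the mean of a gene's detected probes, thresholds of 1.5-fold and 3-fold, the mean of a list, and random lists not matched on expression. The lower bounds in place of differences, and the cornified list without its large families, were added after the data were seen. The procedure was tested on simulated data for this comparison with 16593 genes. All genes changed 4-fold or 8-fold were called (100.0%), as were 38.2% of those raised exactly 2-fold, and 1.99% of unchanged genes. The simulation held technical noise only, without variation between cultures or donors, and its changed genes were drawn from bright probes. These rates therefore give neither the share of false calls between the 2 arrays nor the recovery of dim genes. Of 100 unchanged lists of 20 genes, 3 fell outside percentiles 2.5 to 97.5. These lists were drawn at random from genes with independent noise, so a low share follows from their construction. It does not give the share for lists of genes that vary together. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.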

Results

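Dental epithelial stem cells are the progenitors, kept in the labial cervical loop at the base of the continuously growing mouse incisor, that supply the enamel-forming ameloblasts. Their RNA was compared between mice with Med1 deleted in keratin 14-expressing epithelium and littermate controls, all 3 months old. The comparison addresses which programme, epidermal, hair or dental, the cultured cells express after Med1 deletion. Cells were plated sparsely, so that single stem cells formed colonies, and were kept for 7 days in medium with epidermal and fibroblast growth factors. There was 1 array for each genotype, so every value is a single measurement without replicate error, and their number limits the precision. On the control array 11086 of 25697 probes (43.1%) were detected, and 10935 (42.6%) on the knockout array. The arrays had median signals of 205 and 207 and correlated at 0.93 over the 7272 genes detected on both, a correlation across genes, which are not independent replicates.

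Med1 itself was lower on the knockout array. Its brightest probe read 9.52 on the control array and 8.03 on the knockout array on the log2 scale, 2.81-fold lower. A second, dimmer detected probe differed by -0.28 (6.84 against 6.55), less than the between-probe standard deviation of 0.31. The other 2 Med1 probes were not detected on either array. The position of the probes relative to the deleted exons is not given in the sources used here, and a probe outside them does not check the genotype. No other Mediator subunit differed by 2-fold: of 29 measured, 24 were detected, with a median difference of -0.17 at percentile 18.6 of the random lists. The largest differences in this list were those of Med23 (-0.90), Ccnc (-0.70), Med12 (-0.62) and Med24 (-0.50).

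Of 8217 genes detected on at least 1 array, 686 (8.3%) were at least 2-fold higher on the knockout array and 536 (6.5%) at least 2-fold lower. With the lower bounds for genes detected on 1 array only, 564 were higher and 409 lower. The 12 largest positive differences among genes detected on both arrays included several structural genes of stratified squamous epithelium. They were those of Lyg1, a lysozyme-like gene (149.4-fold), Cdsn, which encodes corneodesmosin, an adhesive protein of the horny layer (95.7-fold), Sprr3, a small proline-rich precursor of the cornified envelope (79.4-fold), Cysrt1 (45.2-fold) and Upk1b, a uroplakin (41.7-fold). Next came the beta-defensin Defb14 (34.5-fold), Lor, encoding loricrin, the main cornified envelope protein (33.2-fold), and Cdkn1c, the cell cycle inhibitor p57 (27.6-fold). Krt13, a keratin of oral mucosa (27.4-fold), Serpinb11 (22.5-fold), Krtdap (19.6-fold) and Sprr1b (17.7-fold) followed. Detected on the knockout array only were Krt4, the partner keratin of Krt13 (at least 112-fold), Defb4 (at least 106-fold), Nccrp1 (at least 63.2-fold), Serpinb3a (at least 44.1-fold), Aif1l (at least 42.7-fold) and Xist (at least 37.9-fold). These sizes depend on background correction. Without it Lyg1 was 51.5-fold higher, Cdsn 41.5-fold, Sprr3 42.0-fold, Krt4 52.1-fold, Defb4 45.4-fold, Nccrp1 24.6-fold and Xist 18.5-fold.

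Among the 12 largest negative differences, Serpina3n, an acute-phase protease inhibitor, was 36.1-fold lower, Cytip 29.4-fold, Sectm1b 26.3-fold, Wfdc18 15.8-fold and Rhox5, an X-linked homeobox gene, 15.6-fold. Ccng2, encoding cyclin G2, was 12.5-fold lower, the neutrophil chemokine Cxcl1 11.6-fold, Nkd2, an inhibitor of Wnt signalling, 11.2-fold, and Prelp, a matrix proteoglycan, 10.7-fold. Ppp1r3c, a glycogen-targeting phosphatase subunit, was 9.0-fold lower, the metalloproteinase inhibitor Timp3 8.6-fold and Dmtn 8.5-fold. Detected on the control array only were Bpifb4 and the chemokine Cxcl5 (each at least 19.2-fold), Lipa, the lysosomal acid lipase (at least 11.7-fold), Dner (at least 11.7-fold), Tesk1 (at least 10.8-fold) and Cbwd1 (at least 10.6-fold). Without background correction these 6 were 4.9-fold (Tesk1) to 7.85-fold (Cxcl5) lower, Serpina3n was 23.8-fold and Cytip 12.2-fold lower. Of the 36 genes with the largest differences, 26 had a fold or bound over 1.5 times the fold without correction, including the 12 detected on 1 array only. Of 219 genes past the 2-fold rule with a further probe detected on at least 1 array, the mean difference of such probes pointed the same way for 211. It did so by 2-fold or more for 157. All probes read the same 2 RNA samples, so this is a check of probes only. The counts depend on background correction: without it 341 genes were higher and 206 lower.

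**Figure D1:**
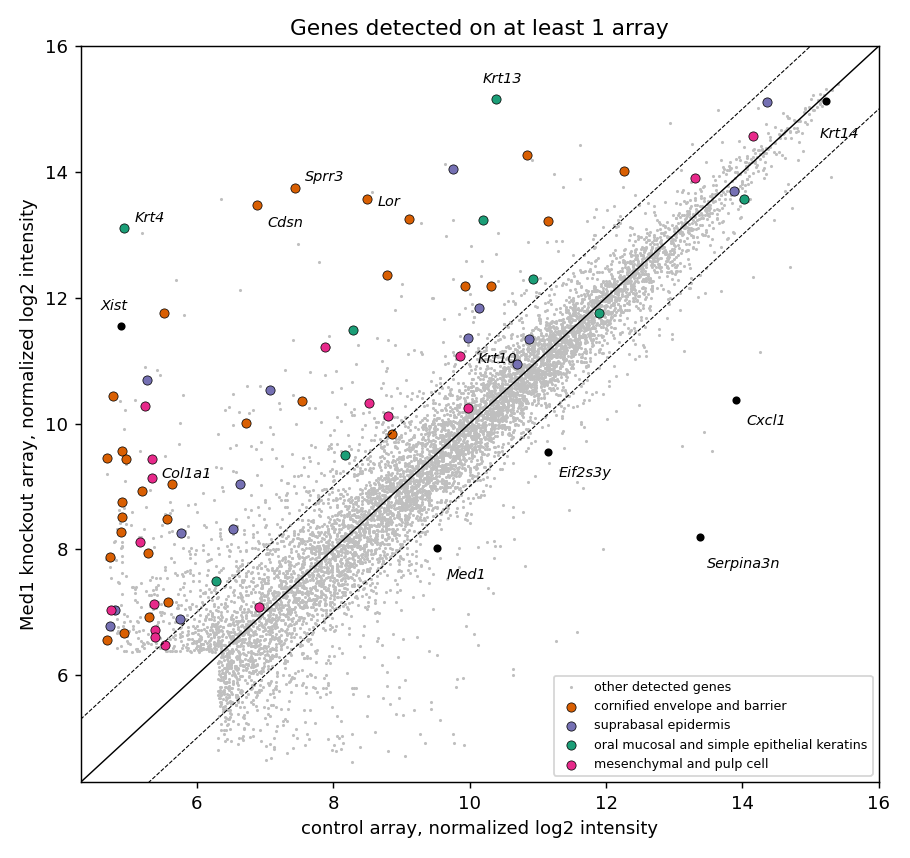
Normalized log2 intensity of each gene detected on at least 1 array, control (x axis) against Med1 knockout (y axis), with a solid line at equal values, dashed lines at 2-fold, members of 4 gene lists in colour and other named genes in black. The cornified envelope genes lie above the upper dashed line in 29 of 30 cases.

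The cornified envelope and barrier genes were higher on the knockout array almost throughout. Of 44 measured, 30 were detected, and 29 of these were at least 2-fold higher and 0 lower. The median difference was 3.39 (1.90 without background correction), at percentile 100, after rounding, of the random lists. The leading members were Cdsn, Sprr3, Serpinb3a and the late cornified envelope gene Lce3c (at least 17.4-fold). With the lower bounds for the 17 members seen on the knockout array only, 25 stayed at least 2-fold higher, with a median of 2.54. The exception was Sprr2a1 (0.97), added here. Among the families, 6 of 7 detected kallikrein (Klk) genes, proteases that include those of epidermal shedding, were at least 2-fold higher and 1 lower (0 with lower bounds), including Klk13 (at least 16.6-fold), Klk14 (at least 17.7-fold) and Klk11 (15.4-fold). All 4 detected beta-defensins (Defb), 4 of 5 Sprr genes and 8 of 9 Lce genes (7 with lower bounds) were at least 2-fold higher.

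Of 19 suprabasal epidermis genes, 15 were detected, 11 were at least 2-fold higher and 0 lower, with a median of 1.78 at percentile 100. Without background correction the median was 0.93, under 2-fold. They included the calmodulin-like Calm4 (at least 20.9-fold), Krtdap, Sbsn (10.9-fold) and the desmoglein Dsg1b (at least 3.88-fold). With lower bounds, 8 were at least 2-fold higher. The log2 difference of Calm4 was 3.25 without background correction, against 4.38 for its bound. Krt10 and Krt1, the keratin pair of suprabasal epidermis, were added here. Krt10 was 2.6-fold higher, and Krt1 was not detected on either array. Of 11 detected transcription factors of epidermal differentiation, 4 were at least 2-fold higher and 0 lower, with a median of 0.84 at percentile 100, and 0.26 when undetected members were included. These were Grhl1 (5.3-fold), Ovol1 (2.6-fold), Elf3 (2.4-fold) and Klf4 (2.1-fold). On the same arrays, markers of mesenchymal cells and Xist were also higher in the knockout, as given further on.

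Basal keratinocyte genes did not move with them. Of 14 detected, 1 was at least 2-fold higher, 2 lower and 11 between, with a median of -0.27 at percentile 1.7. The percentile was 10.6 against random lists not matched on expression and 11.0 with the mean. Krt15 was higher (4.8-fold), the integrin subunit Itga6 was 4.3-fold lower and Krt5 2.3-fold lower, and Bnc1 differed by -0.97. Tfap2c, added here, was at -0.31, with other detected probes from -0.42 to 1.35. Krt14, the partner of Krt5 and the source of the Cre promoter, was added here and differed by -0.10. Of 9 detected keratins and other genes of oral mucosa and simple epithelia, 7 were at least 2-fold higher and 0 lower (median 1.36, percentile 100). Krt4, Krt13, Krt19 (9.2-fold) and Krt23 (8.2-fold) led. The simple epithelial pair Krt8 (-0.45) and Krt18 (-0.13), added here, differed by under 2-fold. The wound and inflammatory genes split. Of 20 detected, 6 were higher and 4 lower, with a median of 0.09 at percentile 88.7. Defb4 and the psoriasin-related S100a7a (a log2 difference of 3.90) were higher, while Cxcl5 and Cxcl1 were lower.

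Hair genes were mostly below detection. Of 26 hair keratin and hair shaft genes measured, 23 were not detected on either array, and neither was any of 30 keratin-associated protein (Krtap) genes. The 3 detected members were Msx2, a homeobox gene (at least 2.68-fold higher), S100a3 (2.6-fold higher) and Krt84 (-0.28). Their median of 1.36, at percentile 97.2, became -0.03 when undetected members were included. Of 8 detected hair follicle stem cell genes, 2 were at least 2-fold higher and 1 lower, with a median of -0.06 at percentile 52.0 and a mean of 0.26. Krt15 and Cd34 (at least 2.18-fold) were higher, Sox9 was 2.0-fold lower and Lrig1 differed by -0.36.

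Enamel genes were likewise mostly undetected and showed no common shift. Of 24 ameloblast and enamel genes measured, 14 were not detected on either array. Of the 10 detected, 1 was at least 2-fold higher and 1 lower, with a median of 0.12 at percentile 85.9. Ambn, encoding the enamel matrix protein ameloblastin, was higher (at least 8.02-fold), and Fam20a, a pseudokinase required for enamel, was 7.1-fold lower, with a second probe at -2.11. The log2 difference of Ambn was 1.74 without background correction, against 3.0 for its bound. Orai1 (-0.35) and Sp6 (0.28) differed by under 2-fold, and the other probes of Sp6 ranged from -0.68 to 0.53. Of 14 detected dental epithelial stem cell and placode genes, 1 was at least 2-fold higher, 2 lower and 11 between, with a median of 0.13 at percentile 89.9. Igfbp5, an insulin-like growth factor binding protein, was 6.6-fold higher. The ectodysplasin receptor Edar was at least 2.60-fold lower, Etv5 was 2.4-fold lower and Dlx2 differed by -0.64. The stem cell factor Sox2, added here, differed by 0.22.

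**Figure D2:**
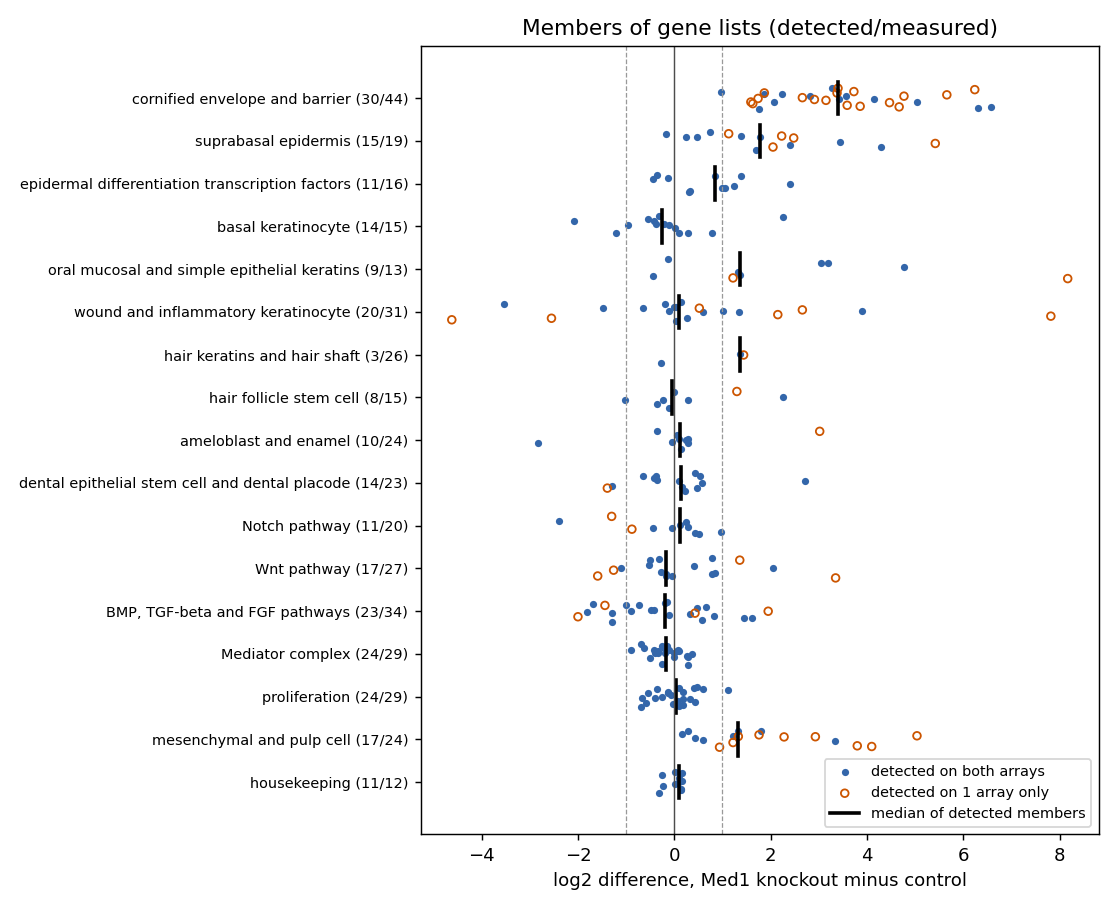
Log2 difference, Med1 knockout minus control, of every detected member of 17 gene lists (y axis, with detected and measured members in parentheses), filled if detected on both arrays and open if on 1, with black bars at list medians and dashed lines at 2-fold. The medians of the cornified envelope (3.39), suprabasal (1.78), oral and simple epithelial (1.36) and mesenchymal (1.33) lists lie to the right of the 2-fold line. So does that of the hair keratin and hair shaft list (1.36), which rests on 3 detected of 26 measured genes. Without background correction the suprabasal (0.93), hair (0.65) and mesenchymal (0.85) medians lie to its left.

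Of 11 detected Notch genes, 0 were at least 2-fold higher and 2 lower (median 0.11, percentile 83.1). The Notch target Hey1 was 5.3-fold lower and the modifier Rfng at least 2.37-fold lower, while Notch4 was at least 1.35-fold lower and Nrarp differed by 0.96. The mean of this list was -0.23, opposite in sign to its median. Of 17 Wnt genes, 3 were higher and 3 lower (median -0.17, percentile 27.1), or 2 higher and 1 lower with lower bounds (median -0.05). Wnt6 (at least 4.25-fold) and Wnt4 (4.1-fold) were higher, Wnt10b was at least 1.68-fold lower and the secreted inhibitor Wif1 at least 1.86-fold higher. The mean of the Wnt list was 0.21. None of 3 detected Hedgehog genes differed by 2-fold (median -0.23, percentile 43.1), with a mean of 0.07. Sufu was at least 1.09-fold higher, Gli3 at least 1.08-fold lower and Smo differed by -0.23. Of 23 BMP, TGF-beta and FGF genes, 3 were higher and 7 lower (median -0.20, percentile 13.0), or 2 and 6 with lower bounds. Tgfb3 was 3.5-fold lower and Fgfr1 at least 1.90-fold lower, and Fgf1 was 3.2-fold lower, while the BMP antagonist Nog was at least 1.97-fold higher.

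Of 16 detected genes of sebaceous and lipid metabolism, 5 were at least 2-fold higher (4 with lower bounds) and 1 lower, with a median of 0.50 at percentile 99.9. Elovl4, which makes the very long fatty acids of the skin barrier, was 6.9-fold higher, Dgat2 2.9-fold and Cidea at least 2.07-fold higher, while the lipogenic regulator Srebf1 was 3.2-fold lower. Among 10 detected vitamin D, calcium and nuclear receptor genes, Rxra alone passed 2-fold (2.1-fold higher), with a median of 0.05 at percentile 72.7. Nr1h3 was at least 1.04-fold lower, and Crabp2 (0.77) and Trpv6 (-0.55) differed by less than 2-fold. Rarg, added here, was at 0.10, with other detected probes at 0.18 and 1.60. Of 24 detected proliferation genes, 1 was 2-fold higher by its brightest probe, Pcna (2.2-fold), and 0 lower, with a median of 0.04 at percentile 82.6. Mcm7 (-0.69), Plk1 (-0.66) and Tyms (-0.59) were next. Mcm6, added here, was at 0.18, but its other detected probes were at 0.01 and 4.87. Of 13 cell cycle inhibitor and senescence genes, 2 were higher and 0 lower (median 0.04, mean 0.49, percentile 78.2). They were Cdkn1c and Perp (3.4-fold), ahead of Gadd45b (0.95) and Igfbp3 (-0.83). Interferon response genes split, with 3 of 18 higher and 3 lower, or 3 and 2 with lower bounds (median -0.29, percentile 12.1). Ifit3 was at least 4.09-fold lower, Oasl1 at least 2.16-fold higher, Isg15 2.6-fold higher and Ifi35 2.4-fold lower.

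Markers of mesenchymal cells were higher on the knockout array. Of 24 measured, 17 were detected, 12 of these were at least 2-fold higher and 0 lower, and the median was 1.33 at percentile 100, or 0.85 without background correction. The surface marker Thy1 (at least 15.7-fold), the collagen Col1a1 (at least 8.82-fold), the proteoglycan Lum (at least 7.13-fold) and Mmp2 (10.1-fold) led. With lower bounds, 8 were at least 2-fold higher and the median was 0.83. The log2 difference of Col1a1 was 2.14 without background correction, against 3.14 for its bound. Col1a2, added here, was not detected on either array. Both detected odontoblast and osteoblast genes of 8 measured were seen on the knockout array only, Ibsp, encoding bone sialoprotein (at least 15.1-fold), and Sp7 (at least 1.55-fold). The log2 difference of Ibsp was 2.96 without background correction, against 3.92 for its bound. Markers of other cell types were few. Of 11 endothelial markers 2 were detected, Flt1 (at least 1.82-fold higher) and Egfl7 (0.80). Of 17 immune markers 3 were detected, with a median of -0.74 at percentile 12.1 that turned to 0.19 when undetected members were included: Coro1a (at least 1.49-fold higher), H2-Ab1 (at least 2.29-fold lower) and Cd14 (-0.74). Of 4 erythroid markers, Hba-a1 was detected on the knockout array only (at least 1.33-fold). Of 10 Schwann, neural and melanocyte markers 4 were detected (median 0.31, or 0.91 over those detected on both arrays, percentile 85.0), with Mbp 4.1-fold higher, Ngfr at 0.91, Pmp22 at -0.29 and Tubb3 at least 1.24-fold lower. Of 11 skeletal muscle markers 2 were detected, Acta1 (at least 1.16-fold higher) and Tnni2 (2.0-fold higher).

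As measures of the samples themselves, none of 11 detected housekeeping genes differed by 2-fold (median 0.09, percentile 85.0). The largest differences were those of Tbp (-0.31), Tubb5 (-0.26), Gusb (-0.24) and Pgk1 (0.16). Actb, added here, was at 0.16 by its brightest probe, but its 4 other detected probes ranged from -2.36 to 0.45. Of 14 early stress genes, 2 were higher and 1 lower (median -0.09, percentile 39.5), with Fos 3.5-fold lower, Atf3 3.1-fold higher, Hspb1 2.3-fold higher and Fosb at least 1.11-fold lower. The sex-linked genes differed between the arrays. Xist, the RNA of the inactive X chromosome, was detected on the knockout array only. The Y-linked genes Eif2s3y (3.0-fold) and Kdm5d (2.8-fold) were lower in the knockout but still detected, and Uty was at least 1.63-fold lower. Usp9y, another Y-linked gene, added here, was detected on the control array only and was at least 3.7-fold lower. The median of the 4 listed genes, Usp9y left out, was -1.41, at percentile 0.1, or -0.68 without background correction, and their mean, which includes Xist, was 0.56 at percentile 88.2.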

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

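The signal bound used for probes without a gene name was chosen after the data were seen. Among the 1719 probes unnamed here, which enter no comparison above, 16 were detected on the knockout array only and at least 2-fold above the lowest detected value of the control array. The opposite holds for 4. Of the unnamed probes, 668 were detected on at least 1 array, and among those detected on both, 32 were at least 2-fold higher and 29 lower on the knockout array. No explanation was tested for these probes.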

How the results depend on the processing

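The lower bounds for genes detected on 1 array and the cornified list without its large families were alternatives chosen after the data were seen. Among 586 recomputed values, a first group covers Med1, the gene counts and the suprabasal, cornified, hair, enamel, dental stem cell, oral keratin and mesenchymal lists. Of this group 85 values, and 341 of the other values, moved by less than the between-probe standard deviation, or by less than 1.5 times for counts, or stayed in the same tail or middle range for percentiles. Beyond that, 40 of the first group and 118 of the others moved, and 1 of each reversed. A value counted as reversed only if it turned sign from a main value of at least 2-fold. Smaller values that turned sign, such as the immune median without a detection filter, count as moved or as unmoved. The between-probe standard deviation is that of single genes and is a loose bound for list medians. The counts of unmoved values therefore do not measure how stable small medians are. Of the 36 top genes, 26 had a fold or bound over 1.5 times the fold without background correction. The count of higher genes (686) was 341 without background correction, 343 with the deposited values, 402 for genes detected on both arrays, 1203 at 1.5-fold and 365 at 3-fold. That of lower genes (536) was 206, 209, 299, 1344 and 204 in that order, and 324 with normexp and offset 50. Median scaling gave 666 higher and 592 lower, and no normalization between arrays gave 631 and 631, so the excess of higher genes depends on the scaling, and also on the threshold, since lower genes outnumber higher ones at 1.5-fold. The Med1 difference (-1.49) was -1.09 without background correction and with the deposited values, and -0.28, -0.16 and -0.01 at its other probes. Without background correction, medians were 0.93 for the suprabasal, 1.90 for the cornified, 0.65 for the hair and 0.85 for the mesenchymal list. With the deposited values they were 0.90, 1.90, 0.63 and 0.83. Normexp with offset 50 gave 1.42, 2.45 and 0.95 for the first 3, and an offset of 50 in neqc gave 1.41 and 2.69 for the first 2. Without a detection filter they were 1.39, 2.16 and, reversed, -0.03 for hair, where 23 undetected genes enter. Lower bounds gave 1.39 for the suprabasal, 2.54 for the cornified and 0.83 for the mesenchymal list, which was 0.90 over genes detected on both arrays. The mean in place of the median gave 0.84 for hair, 2.5 for oral and simple epithelial keratins (1.89 with the mean of probes), 1.91 for mesenchymal and, reversed, 0.56 for sex-linked genes, at percentile 88.2. The sex-linked median (-1.41) was -0.68 without background correction, -0.66 with the deposited values, -0.96 with normexp and -1.09 with lower bounds. The hair percentile was 99.0 against unmatched lists and 88.8 with the mean. The immune median (-0.74) was -0.35 without background correction, -0.34 with the deposited values, -0.22 as a mean and 0.19 without a detection filter. Apart from the alternatives' own construction, the cause was not tested. Background correction widens differences of dim probes, so signal over background limits the folds. No paired analysis was possible because each genotype has 1 array, so no replicate could be left out, and both lie on 1 chip, so no chip block was run. The hair list had too few members detected on both arrays for a value.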

Other observations

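The tests of the cornified, oral keratin, mesenchymal and other-tissue lists, of the second Xist probe and the bound for genes escaping X inactivation were chosen after the results were seen. Symbol families overlap the gene lists, as Col1a1 and Col3a1 stand in the mesenchymal list too, so they are not separate results. Their members may also vary together, unlike those of the simulated lists. Of 34 symbol families, 27 had a percentile, 12 of them in the upper tail and 2 in the lower, at the bounds used for the simulated lists. Among the high ones were collagens (Col, 5 of 20 detected at least 2-fold higher, 4 with lower bounds, 1 lower, median 0.51, or 0.39 with lower bounds), claudins (Cldn, 3 of 12 higher, 1 lower, median 0.51), aldehyde dehydrogenases (Aldh, 3 of 14 higher, 1 lower, median 0.46), glutathione S-transferases (Gst, 3 of 17 higher, 0 lower, median 0.33) and insulin-like growth factor binding proteins (Igfbp, 2 of 5 higher, 0 lower, median 0.96). The low ones were Cxcl chemokines (2 of 5 higher, 3 lower, median -2.66, or -1.27 with lower bounds, percentile 0.0) and Ifi genes (2 of 12 higher, 1 with lower bounds, 3 lower, median -0.55, percentile 0.4). The Rps and Rpl families, which hold the ribosomal protein genes, had medians of 0.03 (Rps) and 0.01 (Rpl), with Rpl29 at 1.18 and its other detected probe at 5.54. Families were matched by symbol prefix alone, so genes outside the named kind can enter, as Cyp26b1 did in the Cyp2 family. Families were recomputed with lower bounds and with the mean, but not under the other normalizations.

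The higher cornified envelope genes were weighed against technical explanations. Shared probes among near-identical paralogs are argued against by the 16 detected members outside the Sprr, Lce and Serpinb families, with a median of 3.33. Normalization is argued against by the lowest median over 6 other normalizations, 1.90. Epithelium of another kind or stage in the knockout culture stays open, because the oral and simple epithelial keratin list was higher too (median 1.36) and each genotype has 1 array. Loss of Med1 is the explanation the design names, as a hypothesis, and it cannot be told apart from such a difference in culture makeup.

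The higher mesenchymal genes (percentile 100) may come from mesenchymal cells in the knockout culture, or from epithelial cells that express these genes, and these cannot be told apart. Of the list, 8 members were also detected on the control array and 2 stand in another list. Of Col1a1, Col1a2, Col3a1 and Sparc, abundant in mesenchyme, 3 were detected on the knockout array and Col1a2 was not. Carry-over of tissue of every kind is also open: 7.5% of 53 endothelial, immune, erythroid, neural and muscle markers (4) were detected on the knockout array only and 2 on the control array only, and the bound for this share was set with these values in view. Of all 16593 genes measured, 439 were detected on the knockout array only and 506 on the control array only. The 4 markers had lower bounds of 1.16-fold (Acta1) to 1.82-fold (Flt1), near the detection floor, so their count does not decide it. Odontoblast and osteoblast genes are outside these 53 markers. Of them, Ibsp and Sp7 were detected, on the knockout array only, Ibsp at least 15.1-fold higher and Sp7 by a smaller bound.

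Xist and the Y-linked genes may differ because female mice were among the knockout donors only, a hypothesis that stays open. Xist was higher and the detected Y-linked genes were lower on the knockout array, the directions this hypothesis gives. A faulty Xist probe is argued against by the second probe, which differed by 5.04. Of genes that escape X inactivation, 3 were detected, Ddx3x (0.48), Eif2s3x (0.55) and Kdm6a (0.04), with a median of 0.48. This lies within the spread of 0.66 that a median of 3 detected genes has on these arrays. The spread rests on the standard deviation of the difference over all detected genes (0.91), which includes genes that differ between the arrays. A smaller shift could not be told by this bound, so the escape genes do not decide the question. Eif2s3y and Kdm5d on the knockout array were at 0.33 and 0.36 of the control level, while Usp9y was not detected there and was at least 3.7-fold lower. The sex of the donors is not given in the sources used here and pooling of their RNA, on which this reading rests, is not stated outright, so a part of any difference between the arrays may be one of sex, which was not tested gene by gene.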
